A study of Homo sapiens with 12 samples.

How the data were processed

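RNA was sequenced from THP-1, a human monocytic leukaemia cell line, in 12 libraries of 4 groups with 3 libraries each. The groups were cells in 2D culture, cells from human skin equivalents (HSE), cells from HSE exposed to UVA (HSE + UVA), and cells from exposed HSE that also received mycosporine-2-glycine (M2G), a mycosporine-like amino acid (HSE + UVA + M2G). Per the labels, an HSE held THP-1 cells and primary dermal fibroblasts in a fibrin gel, with primary epidermal keratinocytes seeded on top and kept at the air-liquid interface for 7 days. The UVA dose was 80 J/cm2 at a distance of 6 cm. M2G was present from 2 h before until 30 min after the exposure, and tissues were harvested 24 h after it. They were digested and sorted for CD45, a surface protein of blood cells. The library kit was Nextera XT, which does not mark the strand of a transcript. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

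The authors deposited 3 tables of 6 libraries, 1 per comparison, that hold a normalised signal per gene, a read count divided by a size factor of the library. HISAT2, SAMtools, HTSeq and DESeq2 1.40.2 were used with the hg19 build, per the submitters' processing notes. The annotation, the trimming and the strand setting are not given in the sources used here. Each table was scaled separately, so tests stayed within a table, and a library has slightly different values in different tables. Genes are named as in the tables, without coordinates, since the reference used here is of another build. Of 21035 genes in any table, 92.0% had a name found in the reference annotation.

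Values were whole multiples of the worth of 1 read for 100.0% of genes in each library (tolerance 0.01 reads), so whole reads could be recovered. Libraries present in a pair of tables gave identical reads at all 19397 genes (HSE) and 19299 genes (HSE + UVA) listed in both. Depth was 6044355 to 9305074 reads per library. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.16 to 36.55, so each library was counted once. Intervals on ratios of reads cover counting error only.

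Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend) on log2(value + 1), two-sided, between the groups of a table and without a replicate block. Genes with a mean value of at least 10 over the table's libraries were tested. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A fold change on this scale understates the change of low genes. HSE + UVA + M2G was compared with HSE on the recovered reads of the 9 HSE libraries in 1 fit, as log2 CPM with a prior count of 1 after TMM scaling with edgeR 4.0.16, since no table used here held both groups. Where a group had no read of a gene, the fold is a lower bound against 3 reads over the group. With 1 to 3 reads in a group, the ratio is given with its exact 95% interval.

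The 29 gene lists, the tests, the rule for named genes and most of the other settings were fixed before the data were examined. Per comparison, the rule took the 6 genes with the highest and the 6 with the lowest log2 fold change among called genes whose groups did not overlap and whose higher group had a mean of at least 100. Empty places went to the genes of smallest unadjusted p that met the other conditions, given as not past the threshold. The rule also took the 2 called members of smallest p in each list with at least 5 tested members, and 14 anchor genes whatever their values. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The list of mitochondrially encoded genes had 0 tested members. Y-linked, XIST and pseudoautosomal genes (46 names) stayed in the fits and counts and are not named. Some genes that the rule took are not reported here, and counts over the rule's genes include them.

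Some genes are uncertain because their exons overlap those of another gene and the counting is not known to use strand. Among those named these are ALYREF, ANKZF1, APEX1, ATP5F1A, BTBD6, CD163, CDKN1A, CYP1B1, FTH1, HLA-C, HMMR, HSPD1, MCM7, MMP1, MMP9, NFE2L2, SERPINB2, SLC6A8, SOD2, TGM2, THBS1, TM4SF1, TNFRSF10B, WDR46 and ZNF585B. Families with near-identical copies may share reads and are likewise uncertain: keratins, HLA genes, metallothioneins, ribosomal protein genes, FTH1, and RNASE2, RNASE3 and ECRP.

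The groups share replicate numbers. Deviations of same-numbered libraries from their group means correlated across genes at -0.04, -0.02 and 0.03 between 2D culture and HSE, at 0.24, 0.50 and 0.17 between HSE and HSE + UVA, and at 0.13, 0.51 and 0.42 between HSE + UVA and HSE + UVA + M2G. By the rule that every pair must exceed 0.1, numbers were taken to pair libraries of HSE groups and not those of 2D culture and HSE. Only libraries of the same number were compared in this way, so nothing is given on libraries of different numbers. Deviations of 3 libraries from their mean cancel out, so a deviation of number 2 alone could also give positive values for numbers 1 and 3. The values therefore do not show that each number forms its own pair. This pairing comes from the data alone, as the labels name no shared day or batch. Values with the replicate number as a block stand beside the results they change.

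The other settings fixed in advance were pseudocounts of 0.5 and 10, no filter, a filter at 50, quantile and TMM scaling, limma without a trend or with sample weights, edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, a replicate block, an absolute log2 fold change of at least 1, and each replicate left out in turn. The fits were tested on simulated data drawn from the real means and library sizes. In the simulation of HSE against 2D culture limma recovered 16.4% of 1.5-fold, 70.1% of 2-fold and 80.3% of 4-fold changes, with 17 false calls. For HSE + UVA against HSE the shares were 1.5%, 44.8% and 83.3%, with 6 false calls, and for HSE + UVA + M2G against HSE + UVA 3%, 26.9% and 80.3%, with 5. The 9-library fit recovered 7.5%, 34.3% and 78.8%, with 7 false calls. In each simulation false calls were a larger share of the calls than the threshold of 0.05 sets. A simulated list of 25 genes with raised members was called with both correlations in each table. The simulated genes varied independently of each other. These calls therefore do not show that an estimated correlation would find a list whose members vary together. A list of random genes was called too in the simulation of HSE against 2D culture (camera adjusted p = 0.0141; adjusted p = 0.0522 with an estimated correlation).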

Results

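Transcripts of THP-1 cells were compared between 2D culture and a human skin equivalent, and within the skin equivalent between no exposure, UVA, and UVA with M2G. Each of the 4 groups had 3 libraries. Depth was 6044355 to 8439030 reads in 2D culture, 7125327 to 7796918 in HSE, 6555640 to 9305074 in HSE + UVA and 7321957 to 7993832 in HSE + UVA + M2G. Values are normalised read counts as mean ± SD (n = 3) unless another unit is named, and adjusted p for genes are from limma.

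The first comparison asked how cells in the skin equivalent differed from cells of the same line in 2D culture. Cells of the HSE were also digested from tissue and sorted, so effects of these steps cannot be told apart from those of the culture. Macrophage, inflammatory and interferon-response genes were far higher in HSE, and cell-division genes were lower. CD163, a scavenger receptor of macrophages, had no read in 2D culture and 4754 ± 2442 in HSE, at least 5071-fold higher (adjusted p = 1.35e-08). C1QB, a complement component, went from no read to 3145 ± 1236, at least 3355-fold. CD14, a co-receptor for bacterial lipopolysaccharide, rose from 10.9 ± 6.11 to 17923 ± 8011 (log2 fold change 10.60, SE 0.45, adjusted p = 6.13e-08). APOE, a lipid carrier protein, rose from 9.42 ± 3.33 to 2987 ± 391 (log2 fold change 8.20, SE 0.22, adjusted p = 4.16e-09). Of macrophage markers, 26 of 30 tested members rose and 1 fell (26 and 1 adjusted over the list alone). CD68 was 2093 ± 368 in 2D culture and 2189 ± 220.3 in HSE and did not pass the test (adjusted p = 0.656). PTPRC, which encodes the sorted protein CD45, rose from 1029.5 ± 169.6 to 1619 ± 381 (adjusted p = 0.00894). MRC1 was too low to test.

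Of inflammatory NF-kB genes, 26 of 28 tested members rose and 0 fell (27 and 0 adjusted over the list alone). TNF, a member of this list, had no read in HSE. The neutrophil chemokine CXCL8 rose from 6.32 ± 2.27 to 4092 ± 2061, and CCL3 and IL1B rose by 8.30 and 8.24 on the log2 scale (8.87 for IL1B without HSE replicate 2). CXCL5 went from no read to 640.4 ± 152. Of interferon-response genes, 35 of 36 tested members rose and 0 fell (35 and 0 adjusted over the list alone). MX1 rose from 46.2 ± 6.13 to 1876 ± 302 and IFI6 from 58.7 ± 4.91 to 4839 ± 1589. Of immediate-early genes, 21 of 22 tested members rose and 1 fell (21 and 1 adjusted over the list alone). DUSP1 rose from 14.3 ± 2.58 to 14163 ± 3725 and JUN from 9.38 ± 3.43 to 1393 ± 446. Of antigen presentation genes, 8 of 12 tested members rose and 0 fell (9 and 0 adjusted over the list alone), with HLA-C and B2M higher by 1.36 and 1.56 on the log2 scale. Of inflammasome genes, 8 of 14 tested members rose and 2 fell (9 and 2 adjusted over the list alone). CASP5 rose from 0.316 ± 0.547 to 65.3 ± 24.6 (209-fold, 95% counting interval 37.5 to 8257).

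Of genes of alternative macrophage activation, 14 of 17 tested members rose and 1 fell (14 and 1 adjusted over the list alone), and the chemokine CCL13 went from no read to 196 ± 67.3. Of LXR and lipid efflux genes, 14 of 17 tested members rose and 0 fell (14 and 0 adjusted over the list alone), and the cholesterol exporter ABCA1 rose from 68.5 ± 22.0 to 2498 ± 356. Of matrix proteases and their inhibitors, 17 of 20 tested members rose and 2 fell (17 and 2 adjusted over the list alone). The collagenase MMP1 rose from 0.268 ± 0.464 to 2530.0 ± 731 (8097-fold, 95% counting interval 1453 to 319812). MMP9 rose 1127-fold (95% counting interval 312 to 9307) to 704 ± 390.1. Of adhesion and matrix receptor genes, 21 of 26 tested members rose and 4 fell (21 and 4 adjusted over the list alone), with THBS1 rising from 1.32 ± 1.43 to 3646 ± 1456 and FN1 from 6.09 ± 2.61 to 1477 ± 509. Fibroblast markers were higher in the same libraries, as given with the skin cell markers. MMP1 was highest in HSE replicate 2, which also had the highest fibroblast share, and the source of its reads was not tested.

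Of G2/M genes, 0 of 24 tested members rose and 24 fell (0 and 24 adjusted over the list alone). CENPF, a kinetochore protein, fell from 1609 ± 72.7 to 433 ± 57.7 and HMMR from 1375 ± 45.9 to 416 ± 49.6. Of S-phase genes, 0 of 24 tested members rose and 23 fell (0 and 24 adjusted over the list alone), and the replication helicase subunits MCM3 and MCM4 fell from 8606 ± 38.6 to 1362 ± 372 and from 5048 ± 464 to 1027 ± 149. CDKN1A, a cyclin-dependent kinase inhibitor, rose from 262 ± 69.2 to 3579 ± 1427 (adjusted p = 2.82e-06). Of p53 targets, 13 of 25 tested members rose and 5 fell (13 and 5 adjusted over the list alone), with SESN2 higher by 2.11 on the log2 scale. Of cytosolic ribosomal protein genes, 0 of 43 tested members rose and 36 fell (0 and 36 adjusted over the list alone). RPS12 fell from 2039 ± 121 to 966 ± 47.0. Of DNA repair genes, 1 of 23 tested members rose and 9 fell (1 and 8 adjusted over the list alone), PARP1 and APEX1 having log2 fold changes of -1.56 and -1.01. Of OXPHOS genes, 1 of 26 tested members rose and 9 fell (1 and 8 adjusted over the list alone), with -0.75 for SDHA and -0.65 for ATP5F1A.

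Of hypoxia and glycolysis genes, 26 of 30 tested members rose and 0 fell (26 and 0 adjusted over the list alone). SLC2A3, a glucose transporter, rose from 7.49 ± 2.38 to 1158 ± 254, and ADM rose from 0.316 ± 0.547 to 929 ± 124 (2974-fold, 95% counting interval 534 to 117454). Of lysosomal genes, 25 of 30 tested members rose and 0 fell (26 and 0 adjusted over the list alone), and the protease CTSD rose from 1273 ± 149 to 10832 ± 1116. Of sterol synthesis genes, 18 of 20 tested members rose and 1 fell (18 and 1 adjusted over the list alone), and DHCR7 rose from 171 ± 76.0 to 1125 ± 23.5. Of integrated stress and unfolded protein response genes, 20 of 24 tested members rose and 0 fell (20 and 0 adjusted over the list alone), and ATF3 rose from 7.49 ± 3.00 to 1453 ± 689 and HERPUD1 from 603 ± 64.9 to 3280.2 ± 360.4. Of NRF2 targets, 21 of 29 tested members rose and 2 fell (22 and 2 adjusted over the list alone). The ferritin chain FTH1 rose from 7097 ± 856 to 111283 ± 36501, PGD from 1686 ± 56.2 to 9039 ± 653 and HMOX1 from 22.6 ± 11.4 to 265 ± 73.4.

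Of myeloid progenitor genes, 9 of 17 tested members rose and 2 fell (9 and 2 adjusted over the list alone), and the granule protein genes CTSG and RNASE3 rose from 3358 ± 665 to 18601 ± 2078 and from 91.7 ± 8.41 to 1142 ± 114. Antioxidant enzymes went both ways. Among them 8 of 24 tested members rose and 7 fell (8 and 7 adjusted over the list alone), with log2 fold changes of 2.11 for GLRX and 3.09 for SOD2. Of heat shock genes, 4 of 16 tested members rose and 4 fell (4 and 4 adjusted over the list alone), with 1.64 for BAG3 and -1.34 for HSPD1. Of metallothioneins, 2 of 5 tested members rose and 0 fell (2 and 0 adjusted over the list alone), with 2.67 for MT2A and 1.41 for MT1X. Of AhR targets, 3 of 5 tested members rose and 0 fell (3 and 0 adjusted over the list alone), with 3.25 for CYP1B1 and 0.98 for NFE2L2.

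Outside the lists, IL1R2, a decoy receptor for interleukin-1, rose from 0.536 ± 0.928 to 13854 ± 8093 (22168-fold, 95% counting interval 6137 to 183051), with a log2 fold change of 13.05, and 13.70 without HSE replicate 2. RNASE1 rose from 1.27 ± 0.562 to 8467 ± 4613, and PRG2, eosinophil major basic protein, from 4.76 ± 1.73 to 16290.5 ± 1603. At the other end CLSTN2 fell from 643 ± 62.8 to 3.76 ± 4.78 and PALD1 from 311 ± 30.3 to 1.69 ± 2.93. FCER2, UGT3A2, ZNF114 and VAT1L had log2 fold changes of -5.80, -5.45, -5.05 and -4.54. Single HSE libraries moved the folds of genes near 0 there. CLSTN2 was at -7.66, and -8.50 and -6.83 without HSE replicate 1 and 2, and PALD1 at -7.41, and -8.28 without HSE replicate 1. Without HSE replicate 2 and 3, FCER2 was at -5.15 and -6.60 and UGT3A2 at -4.80 and -6.25.

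Transcripts of skin cells were higher in HSE as well. Of fibroblast markers, 25 of 27 tested members rose and 0 fell (26 and 0 adjusted over the list alone). Decorin (DCN) rose from 0.370 ± 0.641 to 2680.0 ± 1895 (8577-fold, 95% counting interval 1539 to 338776) and COL6A1 from 45.4 ± 12.2 to 1128 ± 216, while COL1A1 went from no read to 869.9 ± 733, at least 928-fold. Without HSE replicate 2 the HSE means of DCN and COL1A1 were 1593 and 447, the latter at least 476-fold higher. Of keratinocyte markers, 13 of 16 tested members rose and 0 fell (13 and 0 adjusted over the list alone). KRT17 and KRT6A went from no read to 153 ± 88.6 and 155 ± 137 (102 and 79.6 without HSE replicate 3), and KRT14 was too low to test. The fibroblast list made up 0.0537% ± 9.78e-04 of all reads in 2D culture and 0.272% ± 0.128 in HSE (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, and 0.3 adjusted over 6 comparisons). The keratinocyte list made up 0.0122% ± 9.91e-04 and 0.0221% ± 0.00779 (exact permutation p = 0.1, adjusted 0.3). Most of the 2D share came from 2 members of each list. Without IGFBP7 and S100A6 the fibroblast shares were 0.00670% ± 8.21e-04 and 0.187% ± 0.135, and without KRT10 and PERP the keratinocyte shares were 0.00104% ± 3.89e-04 and 0.0104% ± 0.00729 (unadjusted exact permutation p = 0.1 for each). In 2D culture 9 of 28 fibroblast and 5 of 33 keratinocyte markers had a mean of at least 10.

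**Figure D1:**
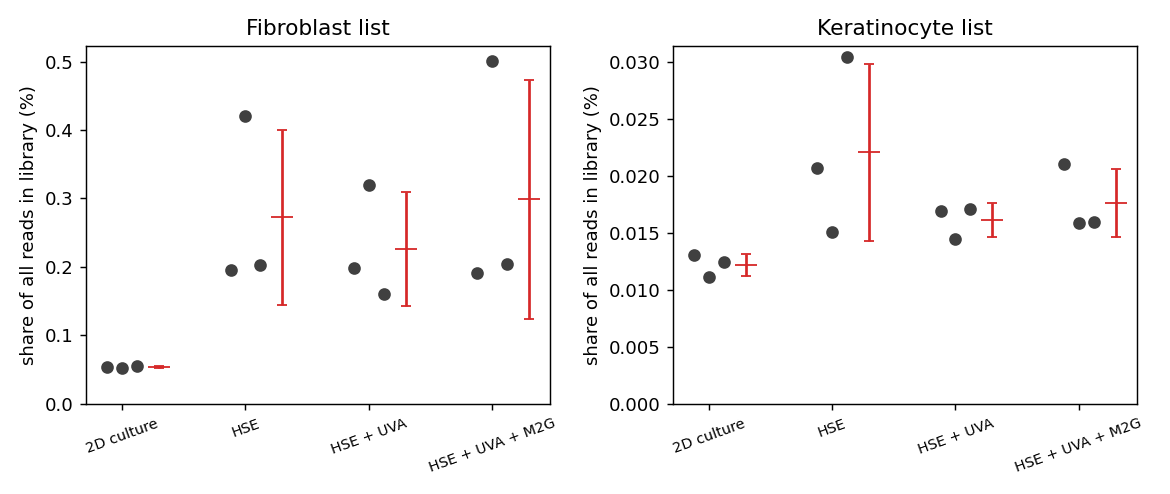
Share of all reads in a library (%) taken by the fibroblast list (left) and the keratinocyte list (right), with 1 point per library and the group mean ± SD in red. The fibroblast share averaged 0.0537% in 2D culture and 0.272% in HSE, and the library numbered 2 was the highest in each HSE group.

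In all, 7283 of 12938 tested genes were called, 3830 higher and 3453 lower in HSE, and 3754 with an absolute log2 fold change of at least 1. The groups did not overlap in 64.1% of genes, against 10% by chance. Camera called 23 of 28 lists, with adjusted p from 1.80e-15 for interferon response to 0.0315 for DNA repair. The antioxidant, heat shock, metallothionein, p53 and AhR lists were not called (adjusted p = 0.607, 0.759, 0.402, 0.0714 and 0.0714). No list call held with an estimated correlation, where adjusted p ran from 0.203 to 0.759. Fry, which tests whether members move 1 way on balance and does not compare a list with other genes, called 27 of the lists, all but heat shock. Quantile scaling moved the median log2 fold change of all genes from 0.03 to -0.18 and gave 3060 higher and 4440 lower genes. The medians of the DNA repair (-0.22) and OXPHOS (-0.20) lists were close in size to that shift, and the DNA repair call was lost under it (adjusted p = 0.0535), while the p53 and AhR lists were called (adjusted p = 0.0336 and 0.0338). A filter at 50 ended the DNA repair and inflammasome calls (adjusted p = 0.0759 and 0.0557). The p53 list was also called without a filter (adjusted p = 0.0394).

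**Figure D2:**
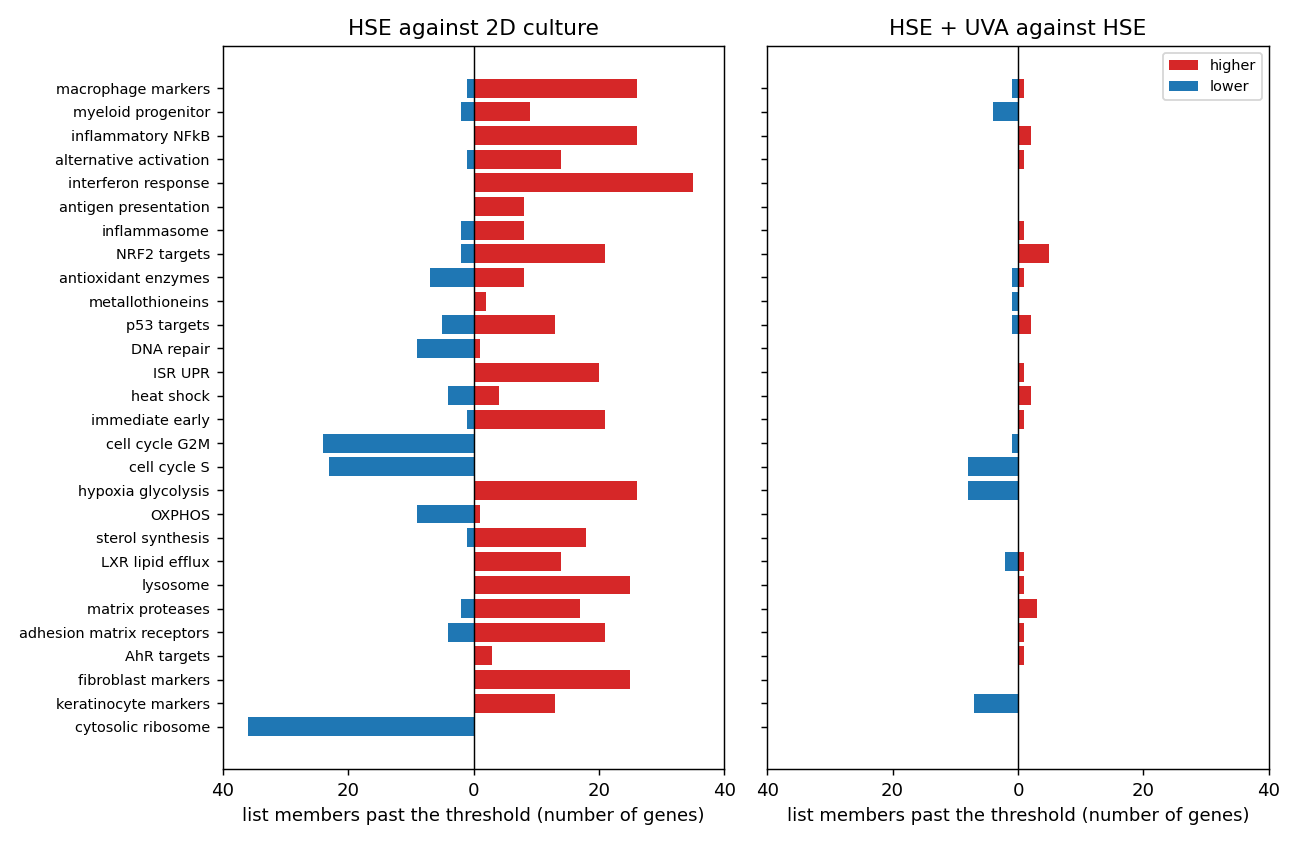
Number of members of each gene list past the threshold in HSE against 2D culture (left) and HSE + UVA against HSE (right), with higher members to the right of 0 and lower members to the left. The interferon-response list had 35 higher members on the left and 0 on the right, and the S-phase list had 23 and 8 lower members.

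The next comparison asked how UVA exposure of the skin equivalent changed the cells inside it. After UVA, 5 of 29 NRF2 target, 2 of 16 heat shock and 3 of 23 matrix protease genes rose, and 8 of 24 S-phase, 8 of 30 hypoxia and 4 of 16 myeloid progenitor genes fell. No call of these 6 lists held with an estimated correlation (adjusted p = 0.439 to 0.488). Fry called 2 lists, NRF2 targets and heat shock (adjusted p = 0.0362 and 0.00681). NQO1, a quinone reductase, rose from 312 ± 71.7 to 1071 ± 295 (log2 fold change 1.76, SE 0.25, adjusted p = 0.0185). AKR1B1, an aldo-keto reductase, rose from 1253 ± 105 to 3070.2 ± 229 (log2 fold change 1.29, SE 0.12, adjusted p = 0.00489), and SRXN1 from 231 ± 3.28 to 532 ± 105. Of NRF2 targets, 5 of 29 tested members rose and 0 fell (16 and 0 adjusted over the list alone), and 20 rose with a replicate block (camera adjusted p = 2.88e-08, and adjusted p = 0.439 with an estimated correlation). HMOX1 was 258 ± 69.9 and 372 ± 74.6 and passed only with the block (adjusted p = 0.179, and 0.0140 with it). Of AhR targets, 1 of 5 tested members rose and 0 fell (2 and 0 adjusted over the list alone), the called member being NQO1, and 5 rose with the block (camera adjusted p = 0.00278, and adjusted p = 0.488 with an estimated correlation).

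Of heat shock genes, 2 of 16 tested members rose and 0 fell (6 and 0 adjusted over the list alone), and 9 rose with the block (camera adjusted p = 1.66e-04, and adjusted p = 0.439 with an estimated correlation). The co-chaperone BAG3 rose from 656 ± 22.8 to 1103 ± 7.74 and HSPH1 from 2535 ± 102 to 3899 ± 496. Of matrix proteases and their inhibitors, 3 of 23 tested members rose and 0 fell (3 and 0 adjusted over the list alone), and 10 rose with the block (camera adjusted p = 0.00135, and adjusted p = 0.488 with an estimated correlation). SERPINB2 rose from 405 ± 90.1 to 1575 ± 649. It was highest in replicate 2 of HSE + UVA (2207) and lowest in replicate 2 of HSE (305), and the source of its reads was not tested. Of adhesion and matrix receptor genes, 1 of 28 tested members rose and 0 fell (6 and 1 adjusted over the list alone), and 13 rose with the block (camera adjusted p = 0.0164, and adjusted p = 0.677 with an estimated correlation). This call was lost with a filter at 50 (adjusted p = 0.172).

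Of S-phase genes, 0 of 24 tested members rose and 8 fell (0 and 21 adjusted over the list alone), and 21 fell with the block (camera adjusted p = 5.14e-11, and adjusted p = 0.488 with an estimated correlation). E2F1, a transcription factor of S-phase entry, fell from 101 ± 29.1 to 18.9 ± 5.37 and MCM7 from 1025 ± 175 to 455 ± 138. Of G2/M genes, 0 of 24 tested members rose and 1 fell (0 and 22 adjusted over the list alone), and 23 fell with the block (camera adjusted p = 6.99e-10, and adjusted p = 0.488 with an estimated correlation). The called member was CDK1, which fell from 559 ± 118 to 275 ± 80.0. Of hypoxia and glycolysis genes, 0 of 30 tested members rose and 8 fell (1 and 21 adjusted over the list alone), and 21 fell and 4 rose with the block (camera adjusted p = 6.60e-08, and adjusted p = 0.488 with an estimated correlation). The lipid droplet protein HILPDA fell from 414 ± 37.1 to 137 ± 26.1 and BNIP3 from 1276 ± 356 to 428 ± 58.6. Of myeloid progenitor genes, 0 of 16 tested members rose and 4 fell (0 and 11 adjusted over the list alone), and 12 fell with the block (camera adjusted p = 4.87e-07, and adjusted p = 0.488 with an estimated correlation). CEBPE, a transcription factor of granulocyte maturation, fell from 86.8 ± 12.4 to 10.3 ± 2.27 (log2 fold change -2.97, SE 0.31, adjusted p = 0.00837), and RNASE3 fell from 1111 ± 116 to 386 ± 181.

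Among other genes, AKAP12, a kinase anchoring protein, rose from 42.9 ± 20.9 to 425 ± 109 (log2 fold change 3.36, SE 0.35, adjusted p = 0.00837), and LPL, lipoprotein lipase, from 96.4 ± 38.8 to 494 ± 204. TM4SF1, GDF15, POPDC3 and PDK4 rose by 3.14, 2.97, 2.45 and 2.27 on the log2 scale. TM4SF1 and GDF15 were highest in HSE + UVA replicate 2 (438 and 396), which also had the highest fibroblast share of that group. POPDC3 and PDK4 were lowest there (192 and 432). Without that library the HSE + UVA mean of TM4SF1 was 167 instead of 257. In HSE, replicate 2 was highest for GDF15 (52.7) but not for TM4SF1 (22.3). The source of these reads was not tested. MIR210HG, the host transcript of a hypoxia-induced microRNA, fell from 175 ± 31.4 to 6.09 ± 3.98 (log2 fold change -4.77, SE 0.43, adjusted p = 0.00422). LOC102724908, ADSS1 and SLC6A8 had log2 fold changes of -2.99, -2.58 and -2.47. IRAK2, CXCL5, TGM2, TXNIP, MGST1, AEN, TNFRSF10B, DDIT4, FOSL1, ATP6V1B2 and ITGB3 also rose, by 0.77 (ATP6V1B2) to 2.35 (ITGB3) on the log2 scale. FCGR1A, MSRA, MT1F and FASN fell, with log2 fold changes of -1.33, -1.61, -1.11 and -1.03.

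Several anchor genes passed only with the block. CDKN1A was 3475 ± 1369 in HSE and 6457 ± 1677 after UVA (adjusted p = 0.112, and 1.50e-04 with the block). CD163 was 4613 ± 2351 and 9558 ± 3513 (adjusted p = 0.153 and 9.32e-05), and MMP1 2463 ± 725 and 5213 ± 2549 (adjusted p = 0.106 and 1.05e-04). MMP1 was highest in replicate 2 of HSE (3240), HSE + UVA (8069) and HSE + UVA + M2G (10939), as was the fibroblast share. Whether the sorted cells or fibroblasts gave the MMP1 reads was not tested. CXCL8 was 3972 ± 1986 and 5834 ± 1424 (adjusted p = 0.306 and 0.0149), and COL1A1 849 ± 721 and 236 ± 136 (adjusted p = 0.111 and 1.26e-04), with an HSE mean of 433 without HSE replicate 2. PTPRC, CD14, CD68, IL1B and MMP9 passed neither way, and TNF, MRC1 and KRT14 were too low to test.

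The OXPHOS list was called lower with no called member (camera adjusted p = 0.0170, and adjusted p = 0.820 with an estimated correlation). The list of integrated stress response genes was called lower too (camera adjusted p = 0.0399, and adjusted p = 0.825 with an estimated correlation), although its 1 called member, DDIT4, rose. With the block 11 of its members fell, and the call was lost without a filter and with camera without a variance trend (adjusted p = 0.0533 and 0.0773). The macrophage, NF-kB, alternative activation, interferon, antigen presentation, inflammasome, antioxidant, metallothionein, p53, DNA repair, immediate-early, sterol, LXR, lysosome and ribosomal lists were not called, with adjusted p from 0.0731 for antigen presentation to 0.817 for DNA repair. Antigen presentation and p53 targets were called higher with the block (adjusted p = 0.0459 and 0.0274, and adjusted p = 0.589 and 0.446 with an estimated correlation). Ribosomal genes were called with quantile scaling (adjusted p = 0.0197), p53 targets without a filter (adjusted p = 0.0171) and antigen presentation with camera without a variance trend (adjusted p = 0.0399). With an estimated correlation and the main settings, adjusted p was 0.897 for ribosomal genes, 0.488 for p53 targets and 0.677 for antigen presentation.

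Of keratinocyte markers, 0 of 17 tested members rose and 7 fell (0 and 9 adjusted over the list alone) after UVA (camera adjusted p = 1.09e-06, and adjusted p = 0.488 with an estimated correlation). KRT17 fell from 148 ± 85.9 to 0.299 ± 0.518, so that HSE was 466-fold higher (95% counting interval 83.6 to 18397). KRT6A fell from 151 ± 133 to 1.15 ± 1.30, a 158-fold difference (95% counting interval 54.0 to 766). The HSE mean of KRT6A was 77.3 without HSE replicate 3, and its log2 fold change of -5.89 was -6.62 and -5.18 without HSE replicate 2 and 3. The fibroblast list had no called member, and 9 lower ones with the block (camera adjusted p = 0.199, and 0.0186 with the block, where adjusted p = 0.597 with an estimated correlation). Fibroblast reads made up 0.272% ± 0.128 in HSE and 0.226% ± 0.0832 after UVA (exact permutation p = 0.6, adjusted 0.6). Keratinocyte reads made up 0.0221% ± 0.00779 and 0.0162% ± 0.00149 (exact permutation p = 0.3, adjusted 0.6). Within pairs of the same number the keratinocyte share was lower after UVA in 3 of 3 and the fibroblast share in 2 of 3 (exact permutation p = 0.25, the smallest that 3 pairs allow, and 0.5). Without PERP and KRT10, the 2 most abundant members, keratinocyte reads made up 0.0104% ± 0.00729 and 0.00143% ± 1.57e-04 (unadjusted exact permutation p = 0.1, the smallest possible).

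**Figure D3:**
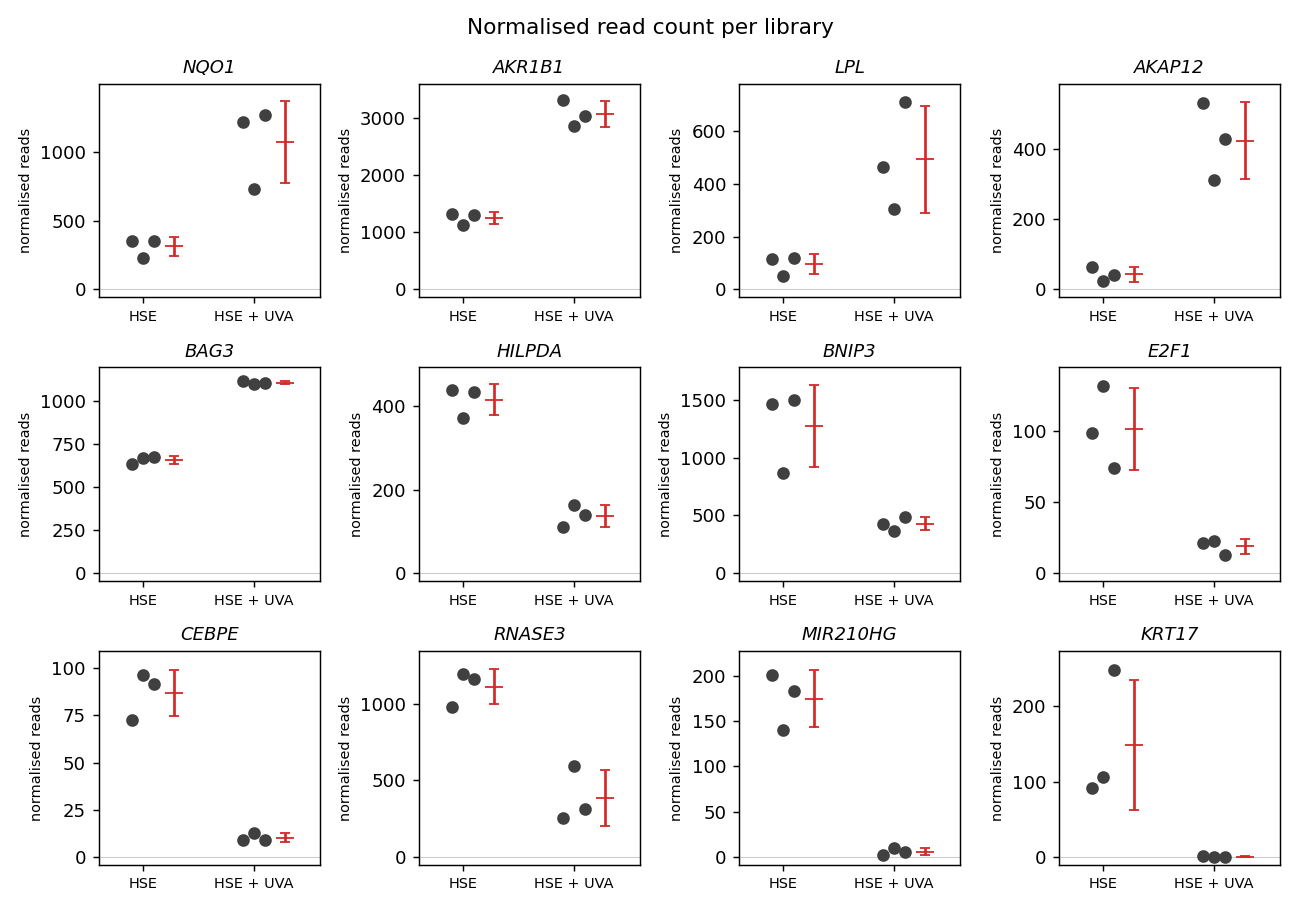
Normalised read counts of 12 genes in HSE and HSE + UVA, with 1 point per library and the group mean ± SD in red. NQO1, AKR1B1, LPL, AKAP12 and BAG3 lay above all HSE libraries after UVA, and HILPDA, BNIP3, E2F1, CEBPE, RNASE3, MIR210HG and KRT17 lay below them.

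In total 428 of 12978 tested genes were called, 192 higher and 236 lower. With the replicate block 2851 were called (1406 higher and 1445 lower), including all 428. The count was 30 without a variance trend, 2225 with sample weights, 1235 with DESeq2, 1448 without number 2 of both groups, 1937 with the fibroblast share as a covariate and 230 with an absolute log2 fold change of at least 1. The groups did not overlap in 30.5% of genes, against 10% by chance. Single libraries decided the count without the block: it was 61, 161 and 0 without HSE replicate 1, 2 and 3, and 5, 1338 and 11 without HSE + UVA replicate 1, 2 and 3. As no gene was called without HSE replicate 3, each of the 41 called genes that the naming rule took for this comparison lost its call there. The largest adjusted p of these genes with 1 library left out ran from 0.0713 to 0.191.

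The M2G comparison asked whether cells under the same UVA dose differed with the compound. No gene passed the threshold among 12858 tested with limma. An unadjusted p under 0.05 was found for 401, a smaller share than the 0.05 that unchanged groups would give on average. The edgeR test called 0 genes (392 unadjusted), and DESeq2 called 1. The smallest adjusted p was 0.436 with limma, 0.318 with edgeR and 0.00133 with DESeq2. Among genes whose groups did not overlap and whose higher group averaged at least 100, those of smallest unadjusted p on the higher side were CDK2AP1 (86.7 ± 15.9 without and 189.6 ± 45.5 with M2G), the kinase AKT1 (358 ± 61.3 and 627 ± 102), ALYREF, BTBD6, FABP4 and CTSZ. On the lower side they were ZNF585B, NFKBIZ (1963 ± 69.5 and 1393 ± 152), ANKZF1, the cytokine OSM (242 ± 13.7 and 159.5 ± 21.7), ZNF805 and TM9SF4. None of these 12 passed (adjusted p = 0.983 for each).

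HMOX1 was 363 ± 74.0 without and 362 ± 24.5 with M2G (log2 fold change 0.01, SE 0.17), and CDKN1A 6311 ± 1635 and 5736 ± 1517 (log2 fold change -0.14, SE 0.25). PTPRC, CD14, CD68, CD163, IL1B, CXCL8, MMP1, MMP9 and COL1A1 did not pass, and TNF, MRC1 and KRT14 were too low to test. The median SE of a log2 fold change was 0.22, and 98.6% of genes had an absolute log2 fold change under 1. The groups did not overlap in 9.02% of genes, against 10% by chance. In simulated data, where few genes were changed, 26.9% of 2-fold and 3% of 1.5-fold changes were recovered. Changes of this size could therefore mostly have been missed if few genes changed.

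With the replicate block 3 genes passed, named here after their values were seen. WDR46 was 6.81 without and 48.8 with M2G (log2 fold change 2.68, adjusted p = 0.0275 with the block). SAP30 was 395 and 775, and TMEM158 325 and 635 (adjusted p = 0.0229 for each with the block). WDR46 was also the gene DESeq2 called. It shares exon positions with another gene, and whether its difference came from the assignment of reads was not tested. In 1 fit of the 9 HSE libraries with the block no gene passed (smallest adjusted p = 0.328).

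Camera called 8 lists with M2G, none with a called member. The ribosomal (median log2 fold change 0.25, adjusted p = 4.75e-11), interferon (0.28, adjusted p = 1.19e-04), macrophage (0.17, adjusted p = 0.00146) and OXPHOS (0.15, adjusted p = 0.00357) lists were called higher. So were the fibroblast (0.38, adjusted p = 0.0163), antioxidant (0.15, adjusted p = 0.0361) and metallothionein (0.24, adjusted p = 0.0473) lists, and the sterol list was called lower (-0.10, adjusted p = 0.00357). No call held with an estimated correlation (smallest adjusted p = 0.783), and fry called 0. Quantile scaling ended the antioxidant and metallothionein calls (adjusted p = 0.0613 and 0.0552), and no filter ended the metallothionein call (adjusted p = 0.129). Camera without a variance trend ended the antioxidant, metallothionein and fibroblast calls (adjusted p = 0.0849, 0.0779 and 0.0662). The keratinocyte list was called without a filter (adjusted p = 0.0379, and adjusted p = 0.830 with an estimated correlation and the main filter). The integrated stress response list was called lower with the block (adjusted p = 0.0494, and 0.102 without; adjusted p = 0.731 with the block and an estimated correlation). The remaining lists were not called under the main settings, with adjusted p up to 0.953 for matrix proteases. Fibroblast reads made up 0.226% ± 0.0832 without and 0.299% ± 0.175 with M2G (exact permutation p = 0.6, adjusted 0.6), and keratinocyte reads 0.0162% ± 0.00149 and 0.0176% ± 0.00297 (exact permutation p = 0.6, adjusted 0.6). Each share was higher with M2G in 2 of 3 pairs (exact permutation p = 0.5 for each). Without PERP and KRT10 the keratinocyte shares were 0.00143% ± 1.57e-04 and 0.00287% ± 0.00281 (unadjusted exact permutation p = 0.9).

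Cells exposed to UVA with M2G were also set against unexposed cells, on recovered reads scaled to a common depth. AKAP12 rose from 42.7 ± 21.0 to 374 ± 133 (log2 fold change 3.16, SE 0.36, adjusted p = 0.00605). GDF15, TM4SF1, POPDC3, MMP10 and LPL rose by 3.09, 3.03, 2.74, 2.65 and 2.64 on the log2 scale. Without HSE + UVA + M2G replicate 2 the changes of GDF15 and TM4SF1 were 2.26 and 2.30. MIR210HG fell from 174 ± 31.8 to 14.2 ± 8.33 (log2 fold change -3.70, SE 0.54, adjusted p = 0.0119). LOC102724908, SPNS3, ECRP, ADSS1 and EPX had log2 fold changes of -2.84, -2.45, -2.44, -2.36 and -2.20. CD163, CDKN1A, COL1A1, HMOX1, MMP1 and PTPRC passed only with the block (adjusted p = 5.85e-04, 0.00229, 0.00107, 0.0314, 0.00324 and 0.0198 with it). CD14, CD68, CXCL8, IL1B and MMP9 passed neither way.

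Of 12991 tested genes, 575 were called in this comparison, 252 higher and 323 lower, and 2380 with the replicate block. The count was 75 and 7 without HSE replicate 2 and 3, 274 and 359 without HSE + UVA replicate 1 and 3, and 222 and 22 without HSE + UVA + M2G replicate 1 and 3. Without HSE replicate 3, AKAP12, POPDC3 and LOC102724908 kept their calls and the other 9 called genes named here lost theirs (adjusted p = 0.0651 for MMP10 to 0.133 for SPNS3). Leaving out any other single library ended calls only among these 9. With HSE + UVA against HSE it shared 247 calls, all in the same direction, where independent lists would share 9.61 in the same direction. In 100 simulations of unchanged groups the comparisons made only 0.06 and 0.03 calls on average, so their overlap, at most 1, cannot show what shared controls add. With 3 control libraries the controls could not be split, so part of the excess may come from them.

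Across 12695 genes, which are not independent replicates, the UVA and M2G changes correlated at r = -0.27 (rho = -0.23). Unchanged groups sharing the HSE + UVA libraries gave r = -0.49 in simulation. Resampling whole libraries of each group, which keeps the relations between genes, gave a mean r of -0.48 with a 95% range of -1 to 0.16, which holds the observed value. The covariance was -0.0455, against a simulated -0.0593. The culture and UVA changes correlated at r = 0.01 across 12591 genes (rho = 0.05), against a simulated -0.50 and a resampled -0.46 with a 95% range of -1 to 0.0201, which also holds the observed 0.0134. Their covariance was 0.0124, against a simulated -0.0529. Of genes called in both, 150 changed in the same and 174 in opposite directions, where independent lists would give 118 and 121. Those expected counts leave out the HSE libraries, which the comparisons share on opposite sides, and so are not the counts without an effect.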

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

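Chosen after seeing the data were the 9-library fits of single comparisons, the fits without number 2 of both groups, the fibroblast covariate, camera without a variance trend, the skin cell shares within pairs and the collagen ratio with libraries left out. For HSE against 2D culture 7283 genes became 3754 with an absolute log2 fold change of at least 1. All other counts run lay within 1.5 times, 6272 to 7227 with 1 replicate left out, and none of 70 called genes that the naming rule took lost its call then. The replicate block gave 7027 and added the AhR list (adjusted p = 0.0338), but numbers do not pair these libraries. For HSE + UVA against HSE 428 genes became 30 without a trend, 2225 with sample weights, 1235 with DESeq2, 2851 with the replicate block, 230 with the fold threshold, 1448 without number 2 of both groups, 2257 with 9 libraries and the block, 1937 with the covariate, and 0 to 1338 with 1 replicate left out. The cause was not tested beyond the block and the covariate. For M2G, 0 genes became 1 without a trend (WDR46), 1 with DESeq2, 3 with the replicate block and 1 with the covariate (CSF2, named after its values were seen). With 9 libraries and the block 0 were called (smallest adjusted p = 0.328), and the count stayed at 0 with 1 replicate left out. For HSE + UVA + M2G against HSE, 575 genes became 2380 with the block and 7 to 806 with 1 replicate left out. An estimated correlation left 0 called lists in each of the 3 comparisons, and camera without a variance trend 5 of 8 for M2G. The correlation of culture and UVA changes was -0.0156 with edgeR and 0.0856 with a filter at 50. The resampled range was run with the main filter only, where its upper limit was 0.0201. Over the genes of that rule and the alternatives, 194 calls were lost and 26 gained for UVA, 29 and 6 for HSE + UVA + M2G against HSE, and 0 otherwise. The block changed no other list call than those given, and no other call of a gene in the comparison for which the rule took it. CTSG, taken for culture, passed for UVA only with the block (adjusted p = 0.0570, and 3.36e-04 with it). In the simulations, where few genes were changed, 1.5-fold changes were mostly not recovered. The adjusted threshold is less strict where many genes change, so this does not carry over to HSE against 2D culture. There ATP5F1A (1.57-fold, limma adjusted p = 3.84e-04) and PTPRC (1.56-fold, limma adjusted p = 0.00894) passed.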

Other observations

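The tests on the co-variation of fibroblast and keratinocyte markers, the same-number correlation, the collagen ratio and the fibroblast covariate fit were chosen only after results were seen.

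Single genes chosen after their values were seen are given as values only. EPX, eosinophil peroxidase, was 0.316 ± 0.547 in 2D culture and 349 ± 99.5 in HSE. In the separately scaled table of the UVA comparison, which holds the same HSE libraries, it was 339.6 ± 96.5 in HSE and 117 ± 70.0 after UVA. The defensin gene DEFA4 was 90.7 ± 57.0 and 7.03 ± 2.58 there. MPO, myeloperoxidase, did not pass for culture or for UVA. MS4A3 did not pass for culture, and for UVA it passed only with the replicate block (3278 ± 1203 in HSE and 947 ± 690 after UVA). In M2G libraries WDR46 was 49.2, 45.5 and 51.7, against 7.92, 6.30 and 6.21 with UVA alone.

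Fibroblast and keratinocyte markers were present in libraries sorted for CD45, a sort meant to remove both cell types. Over the 9 HSE libraries the deviations of fibroblast markers from group means had a median pairwise correlation of 0.816, against a 95th percentile of 0.061 in random lists matched on level. This is consistent with varying amounts of RNA or cells of fibroblasts, as a hypothesis. Keratinocyte markers gave 0.589 (95th percentile 0.175), but in HSE the basal keratins KRT5 and KRT14 averaged 2.02 and 3.75 beside 148 for KRT17. RNA of keratinocytes and expression of these keratins by the sorted cells therefore cannot be told apart. KRT6B, KRT16 and SPRR1B averaged 53.3, 46.7 and 64.1 in HSE and 0.536, 0.299 and 0.268 after UVA, while KRT10 averaged 467 and 442. KRT17 was 77.9 in HSE + UVA + M2G replicate 1 and 0.967 and 1.12 in replicates 2 and 3. KRT6A was 73.8, 0 and 1.12 in these libraries, and SPRR1B 37.9, 0 and 0.

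The replicate block raised the count for UVA from 428 to 2851 genes. A difference shared by libraries of the same number may account for this, since the lowest same-number correlation of HSE groups was 0.127. A deviation of number 2 alone could also give such values. Different amounts of fibroblast RNA are another candidate explanation, since the fibroblast share as a covariate gave 1937 calls. Replicate 2 had the highest fibroblast share in each HSE group, so the number and the share overlap. No biological explanation was tested.

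Collagen markers were lower against the other fibroblast markers after UVA. The log2 ratio of their reads differed by -0.52 between the 6 exposed and the 3 HSE libraries (exact permutation p = 0.0357 over 84 splits), below HSE of the same number in 6 of 6. HSE replicate 2 (-0.34) carried much of this, as the difference was -0.20 without it, and HSE + UVA replicate 2 (-1.16) lay above HSE replicates 1 and 3 (-1.32 and -1.28), so this ratio alone excludes nothing. Over the 6 collagen and 13 other markers with a mean under 10 in 2D culture, it differed by -1.42 (-1.07, -1.55 and -1.63 within the numbers), and -1.22 without HSE replicate 2, with no overlap (exact permutation p = 0.0370 within numbers, the smallest that 27 arrangements allow). These last values argue against fewer fibroblast transcripts as a whole as the only cause if all these markers came from fibroblasts in HSE. A low mean in 2D culture does not show this, and the source of each marker was not tested. The restriction to these markers was also chosen after results were seen. The p within numbers takes same-numbered libraries as paired, which the labels do not state. Lower collagen expression after UVA and a change in which fibroblasts or transcripts reached the sorted samples both stay open.

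The 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. For HSE against 2D culture the real split gave 7283 genes, for HSE + UVA against HSE 428, and for HSE + UVA + M2G against HSE 575. In each, 1 of 10 splits gave as many, and the highest of the others gave 0. For M2G the real split gave 0, as did all 10. With the block, 4 splits part all 3 pairs, also too few. There the real split gave 2851 genes for UVA and 3 for M2G, the highest other gave 0, and 1 of 4 gave as many in each.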
